A study of Mus musculus with 24 samples.

How the data were processed

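RNA was measured in 24 libraries from TCRα-/- mice bearing pancreatic organoid tumors, in 8 groups of 3 made by tissue (spleen, tumor), sorted population (CD45+CD4+, CD45+CD8+) and treatment (vehicle, LCL161). Per the submitters' processing notes, total RNA was extracted with a Qiagen kit, libraries were made with Illumina protocols, adapters were trimmed with cutadapt, and reads were aligned to GRCm38 with STAR 2.7.3a. The authors deposited one table of expected counts per gene, 55025 gene symbols by 24 columns, and every column was matched to a sample. The counting tool, the annotation and the strand setting are not given in the sources used here. Of the non-zero values 52.7% are not whole, and they were rounded before testing. No gene symbol was missing, 36303 symbols had a count, and 53522 are in GENCODE M21, from which coordinates and overlaps between genes were taken. Library totals ran from 15.5 to 25.1 × 1e6 counts. No pair of replicates agreed within counting error, with a chi-square per gene of 13.01 to 134.69 over the 24 pairs and the genes with at least 20 counts in a pair, so no pair was counted as 1 library. No library was left out.

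Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), which left 20203, and libraries were scaled by TMM (factors 0.94 to 1.05). One robust quasi-likelihood model with a mean per group was fitted to all libraries, with 16 residual degrees of freedom, a median prior of 2.7 and a common coefficient of biological variation of 0.33. There were 12 contrasts: LCL161 against vehicle in each population (4), the differences of those effects between tissues (2) and between populations (2), tumor against spleen in vehicle libraries (2), and CD8 against CD4 in vehicle libraries (2). P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Levels are CPM on TMM-scaled library sizes, and log values used a prior count of 2. A fold against a group with no count is a lower bound against 3 counts per library. The 36 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with a correlation estimated from the data, and with the rotation test fry. Members of each list were also counted with p-values adjusted over the list alone.

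Named genes follow a rule. Among genes past the threshold whose groups do not overlap and whose higher group has at least 5 CPM, the 10 largest rises and falls are named, leaving out predicted genes, clones, pseudogenes, variable, diversity and joining segments of receptors and immunoglobulins, and mitochondrial genes. For differences of effects the overlap condition was dropped and 5 each way are named. Up to 4 members per list with the smallest adjusted p and a panel of 22 genes were added, and the text gives part of all these in that order. Contrasts, lists, the rule and all alternatives but one were fixed before the data were examined. The pattern that applies the rule first missed gamma chain variable segments under the symbols Tcrg-V, and was corrected after their values had been seen, with all results rebuilt.

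The alternatives were RLE scaling, no scaling, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom with sample weights, only the libraries compared, each library left out in turn, a log2 fold change of at least 1, a block for the replicate number, and LCL161 libraries in place of vehicle for the contrasts between tissues and populations. Marker scores of other cells as covariates were added after the data were seen. The pipeline was tested on simulated data with 200 changed genes. In spleen CD4, spleen CD8, tumor CD4 and tumor CD8, edgeR recovered 44.8%, 44.8%, 37.3% and 38.8% of genes changed 2-fold and 84.8%, 72.7%, 81.8% and 86.4% of those changed 4-fold, and called 1, 8, 5 and 5 genes that were not changed. DESeq2 called 160, 150, 140 and 150 genes, of which 31, 34, 22 and 25 were not changed, and limma voom called 7, 11, 13 and 8 such genes. A list shifted 2-fold was recovered by each of the list tests, with 0 of 33 other lists called by camera at either correlation or by fry. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera at the preset correlation calls lists whose members vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.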

Results

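To follow how blocking cIAP1 and cIAP2 changes T cells in a tumor-bearing mouse, RNA was sequenced from cells sorted as CD45+CD4+ or CD45+CD8+ out of the spleen and the tumor. All animals were TCRα-/- mice, in which the gene for the alpha chain of the T cell receptor is disrupted, and no wild-type group is in the series. They carried pancreatic tumors grown in the pancreas from M8 organoids, cultured tumor cell clusters whose origin is not given in the sources used here. LCL161 mimics the protein SMAC and drives cIAP1 and cIAP2 to degradation. It was given by mouth at 75 mg/kg from day 4 at intervals of 3 days, and tissue was taken on day 12 after 3 doses. The 24 libraries form 8 groups of 3. Total counts in units of 1e6, for replicates 1, 2 and 3, were 20.3, 19.2 and 18.2 for spleen CD4 vehicle, 21.6, 23.5 and 22.8 for spleen CD4 LCL161, 22.5, 22.8 and 20.7 for spleen CD8 vehicle and 20.3, 18.2 and 20.3 for spleen CD8 LCL161. In the tumor they were 21, 19 and 25.1 for CD4 vehicle, 22.7, 19 and 22.6 for CD4 LCL161, 23, 24.3 and 22.7 for CD8 vehicle and 17, 15.5 and 18 for CD8 LCL161. Labels do not say that replicates are separate mice, so p-values measure spread between samples, pooled per gene over all 8 groups. Levels are CPM (counts per 1e6 counts of the scaled library), mean ± SD, and log2 fold changes carry their SE, with n = 3 libraries a group throughout. Gene p-values come from edgeR's quasi-likelihood test, adjusted over the 20203 genes tested, and list p-values from limma's camera. Of unadjusted p-values, chance alone puts a share of 0.05 under 0.05.

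To see whether the sort and the genotype show in the libraries, the receptor genes were read before any comparison. The targeted gene Trac (chromosome 14, 54220521 to 54224206, GRCm38) had 293, 573 and 119 CPM in the spleen CD4 vehicle libraries and 1080, 758 and 352 CPM in spleen CD4 LCL161. In tumor CD4 it had 63.1, 403 and 548 CPM with vehicle and 827, 553 and 363 CPM with LCL161. The CD8-sorted libraries held less Trac, with 9.29, 11.1 and 10.6 CPM in spleen vehicle, 12.2, 21.1 and 20.2 CPM in spleen LCL161, 23.5, 18.2 and 20.4 CPM in tumor vehicle and 19.7, 35.4 and 21.7 CPM in tumor LCL161. The deleted part of the gene is not given in the sources used here, so this level does not check the genotype. Joining segments of the alpha chain, which appear in RNA after rearrangement, summed to 35.6 ± 21.8 CPM in spleen CD4 vehicle and 39.2 ± 30.5 CPM in tumor CD4 vehicle, against 0.121 ± 0.0919 CPM in spleen CD8 vehicle and 0.233 ± 0.14 CPM in tumor CD8 vehicle. Trdc, the constant gene of the delta chain, stood at 305 ± 254 CPM in spleen CD4 vehicle, 630 ± 65.3 CPM in spleen CD8 vehicle, 216 ± 286 CPM in tumor CD4 vehicle and 1380 ± 259 CPM in tumor CD8 vehicle. Cd4 (chromosome 6, 124864692 to 124888221) reached 1180 ± 276 CPM in spleen CD4 vehicle and 10.2 ± 3.08 CPM in spleen CD8 vehicle. Cd8a (chromosome 6, 71373427 to 71379173) had 2.13 ± 1.61 CPM in spleen CD4 vehicle and 599 ± 20.2 CPM in spleen CD8 vehicle. Cd3e, a chain of the receptor complex, was present in every group, from 540 ± 23.7 CPM in spleen CD8 vehicle to 1150 ± 363 CPM in spleen CD4 LCL161. Markers of other cells were also read in the sorted populations. B cell and plasma cell markers summed to 9460 ± 2520 CPM in spleen CD8 vehicle, dendritic cell markers to 4310 ± 168 CPM there, and monocyte and macrophage markers to 8510 ± 3470 CPM in tumor CD4 vehicle.

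**Figure D1:**
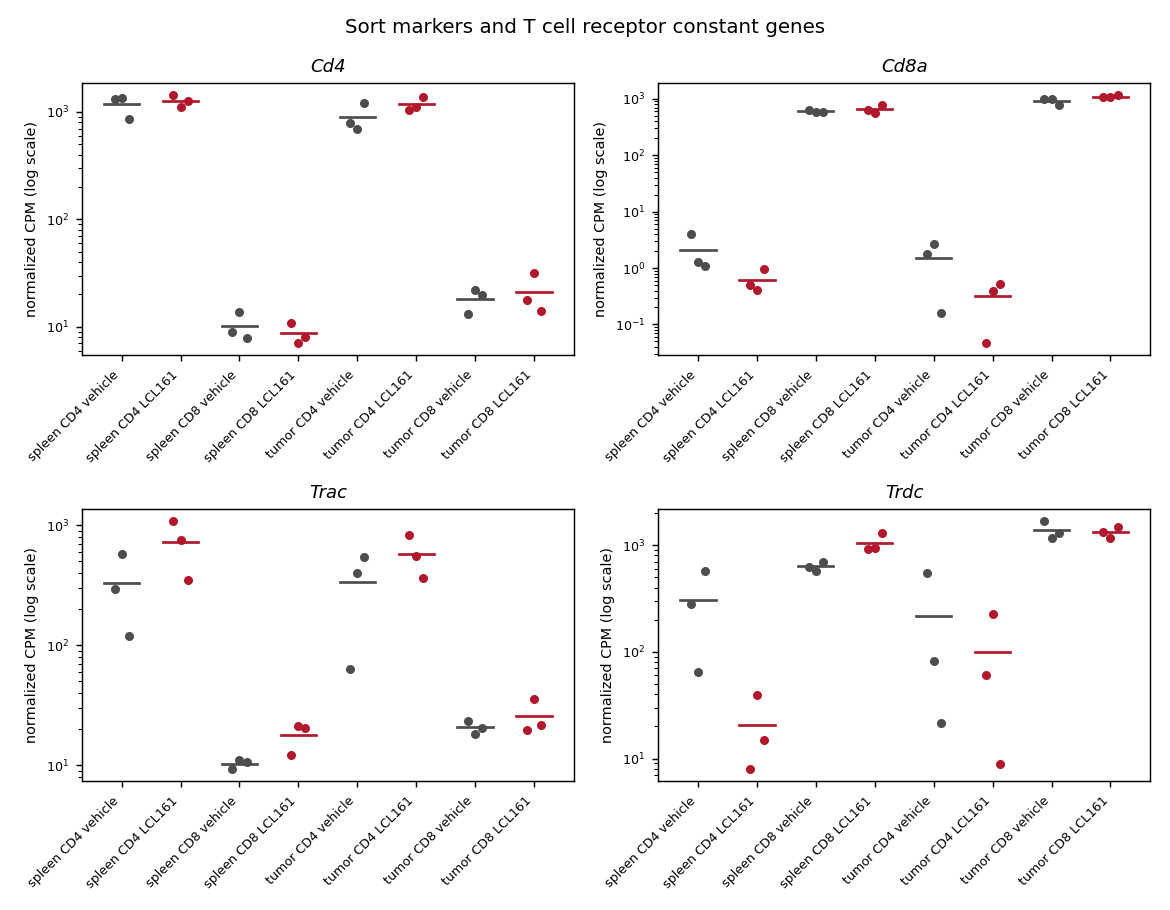
Normalized CPM (log axis) of Cd4, Cd8a, Trac and Trdc in the 8 groups; points are the 3 libraries, lines the group means, vehicle in grey and LCL161 in red. Mean Trac lies at 328 CPM in spleen CD4 vehicle and at 10.3 CPM in spleen CD8 vehicle.

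The study's central question is what LCL161 does to T cells, taken up here in CD4-sorted cells of the spleen. Among the rises were genes of the NF-kB pathway. Nfkb2, which encodes the p100 precursor of the alternative pathway, went from 172 ± 16.7 to 451 ± 158 CPM, 2.62-fold higher (log2 fold change 1.39 ± 0.24, adjusted p = 0.024). Nfkbia, which encodes the inhibitor IκBα, went from 286 ± 14.1 to 764 ± 192 CPM (1.42 ± 0.19, adjusted p = 0.0055). Relb rose by 1.09, Birc3, the gene of cIAP2, by 0.79, Traf1 by 1.15 and Bcl3 by 1.21 on the log2 scale. Of the gamma delta receptor genes Tcrg-C2 fell from 294 ± 197 to 25.3 ± 13.3 CPM (adjusted p = 0.042), while Trdc, at 305 ± 254 and 20.8 ± 16.5 CPM, did not pass (adjusted p = 0.11). Of 20203 genes, 48 were higher and 40 lower, 66 of them by at least 2-fold. Of the 88 genes 87 had groups that did not overlap, as had 14.6% of all genes tested against 10% by chance. The largest rises on the log2 scale were Il1r2 (3.05), Cxcl10 (2.64), Tnfrsf4 (2.34), C1qtnf12 (2.17), Zc3h12a (1.89), Mt1 (1.85), Nt5dc2 (1.72), Arc (1.58), Per1 (1.58) and Sdhaf1 (1.57) (adjusted p 0.02 to 0.048). Il1r2 encodes a decoy receptor for interleukin 1, Tnfrsf4 the costimulatory receptor OX40, and Zc3h12a an RNase that limits cytokine transcripts. The largest falls were Tcrg-C2 (-3.53), Mras (-3.41), Mrc1 (-2.91), Sirpb1a (-2.79), Apol7c (-2.71), Appl2 (-1.88), Itprid2 (-1.57), Pik3r5 (-1.48), Tob1 (-1.42) and Cd7 (-1.41) (adjusted p 0.014 to 0.049). Trgv2 also fell by 3.77, and Tnfrsf18 rose by 1.40, Junb by 1.18, Icam1 by 1.08, Batf by 1.32, Socs1 by 1.35 and Myc by 1.22. Birc2, the gene of cIAP1, stood at 78.8 ± 2.92 and 76.2 ± 24.8 CPM (adjusted p = 0.94), Ifng at 39.5 ± 9.02 and 98.3 ± 86.9 CPM (0.32) and Gzmb at 109 ± 99.6 and 42.7 ± 16.6 CPM (0.31).

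As gene groups in spleen CD4, the classical NF-kB targets were higher (median 0.64, camera adjusted p = 1.4e-07 and adjusted p = 0.39 with an estimated correlation). Over all genes 4 higher of 21 members passed, and 11 higher and 1 lower adjusted over the list alone. The alternative NF-kB pathway genes did not pass camera (median -0.04, camera adjusted p = 0.054 and adjusted p = 0.39 with an estimated correlation) and had 4 higher of 15 members over all genes, 4 higher adjusted over the list alone. Oxidative phosphorylation genes were higher by a small amount (median 0.30, camera adjusted p = 7.2e-10 and adjusted p = 0.39 with an estimated correlation). Among 38 members 0 passed over all genes and 16 higher adjusted over the list alone. The gamma delta T cell markers were lower (median -2.76, or -2.44 with members at 0 in a group taken at their bound, camera adjusted p = 2.4e-06 and adjusted p = 0.39 with an estimated correlation). This list has 14 members, with 2 lower over all genes and 7 lower adjusted over the list alone. Cytotoxic effector genes were lower too (median -0.94, camera adjusted p = 0.0011 and adjusted p = 0.41 with an estimated correlation). In it 0 of 21 members passed over all genes, and 3 lower adjusted over the list alone. Among markers of other cells, those of plasmacytoid dendritic cells were lower (median -1.15, camera adjusted p = 5.6e-05 and adjusted p = 0.39 with an estimated correlation) and those of neutrophils higher (median 2.08, camera adjusted p = 5.8e-05 and adjusted p = 0.39 with an estimated correlation). CD8 lineage genes were lower (median -1.14, camera adjusted p = 0.0015 and adjusted p = 0.39 with an estimated correlation), with 0 of 10 members over all genes, 7 lower adjusted over the list alone, and so were NK cell markers (median -0.97, camera adjusted p = 0.0017 and adjusted p = 0.39 with an estimated correlation), with 0 of 12 members over all genes, 0 adjusted over the list alone, while CD4 lineage genes did not pass (median 0.61, camera adjusted p = 0.058 and adjusted p = 0.39 with an estimated correlation). Of the 36 lists 19 passed camera at its preset correlation of 0.01 and 0 with an estimated correlation. The count of 88 became 16 without vehicle replicate 1, 226 without vehicle replicate 2, 7 without vehicle replicate 3, 0 without LCL161 replicate 1 and 225 without LCL161 replicate 3. There 5, 25, 4, 0 and 25 of the 33 named genes past the threshold remained. It was 651 (309 higher, 342 lower) by DESeq2, 2 (2 higher, 0 lower) by limma voom, 0 with the 6 libraries fitted alone (the unadjusted p was under 0.05 for 1417 genes there), 49 without a filter on low counts and 52 with marker scores of other cells as covariates.

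**Figure D2:**
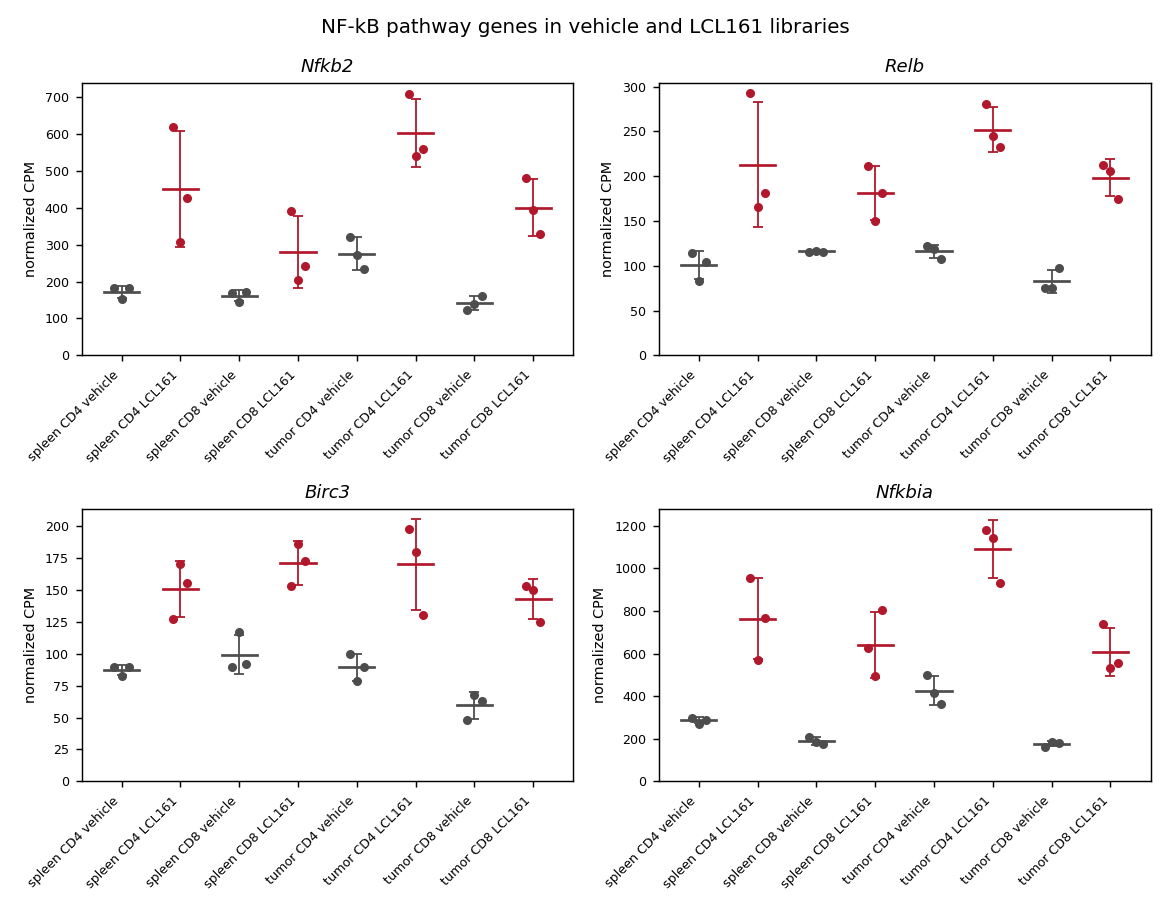
Normalized CPM of Nfkb2, Relb, Birc3 and Nfkbia in the 8 groups; points are the 3 libraries, lines the group means and bars ± SD, vehicle in grey and LCL161 in red. The LCL161 means of Nfkbia exceed the vehicle means in all 4 populations, with 176 against 607 CPM in tumor CD8.

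The same question was put to CD8-sorted cells of the spleen. Gzmb (chromosome 14, 56258838 to 56262260), which encodes the cytotoxic protease granzyme B, went from 83.5 ± 29.4 to 553 ± 306 CPM (6.62-fold, log2 fold change 2.73 ± 0.66, adjusted p = 0.018), and Ifng (chromosome 10, 118441046 to 118445892), the gene of interferon gamma, from 10.3 ± 4.05 to 63.8 ± 34.2 CPM (2.63 ± 0.67, adjusted p = 0.023). The NF-kB target gene Nfkbia (chromosome 12, 55489410 to 55492647) rose from 190 ± 18 to 642 ± 155 CPM (1.76 ± 0.19, adjusted p = 8.7e-05). Wdfy4, a dendritic cell gene needed for cross-presentation, fell from 732 ± 13.3 to 73.6 ± 26.7 CPM (-3.32 ± 0.57, adjusted p = 0.0026) and the chemokine receptor gene Xcr1 from 346 ± 18.3 to 71.2 ± 53.9 CPM (-2.28 ± 0.57, adjusted p = 0.021). In all, 830 genes were higher and 852 lower, 749 of them by at least 2-fold. RLE scaling gave 656 and 913, no scaling beyond the library totals 972 and 806, and marker scores as covariates 53 and 275, so which direction holds more genes depends on these choices. Separate groups, with no library of one reaching into the other, were found for 1651 of the 1682 genes and 38.9% of all genes, against 10% by chance. The largest rises on the log2 scale were Clgn (3.75), Cables1 (3.52), Arg1 (3.27), Nfkbiz (3.03), Gzmb (2.73), Ifng (2.63), Cxcl10 (2.61), Serpina3f (2.52), Tnfrsf9 (2.52) and Tigit (2.47) (adjusted p 0.00051 to 0.036). Tnfrsf9 encodes the costimulatory receptor 4-1BB and Tigit an inhibitory receptor of T and NK cells. The largest falls were Rtl5 (-4.16), Ltbp2 (-4.15), Cd209e (-3.55), Lrrc25 (-3.44), Apol7c (-3.33), Wdfy4 (-3.32), Anpep (-3.27), Alpk1 (-3.16), Klf4 (-3.08) and Notch4 (-3.03) (adjusted p 0.00012 to 0.046). Cd69, an early activation gene, rose by 2.02, Fasl by 1.60, Lta by 1.43, Tnfrsf18 by 1.27, Batf by 1.36 and Birc3 by 0.78, and Zbtb7b, whose product directs the CD4 fate, fell by 1.68. Map3k14, the kinase gene of the alternative NF-kB pathway, fell by 1.26 (adjusted p = 0.0092), while Nfkb2 (chromosome 19, 46304320 to 46312385) rose by 0.79 (0.047) and Relb by 0.64 (0.036). Trem2 and Krt19, which mark macrophages and ductal cells, had no count in the vehicle libraries and were at least 3.76-fold and 2.99-fold higher, measured against a floor of 3 counts per library. Such floors cover counting error only. Genes encoded in mitochondria took 1.46 to 1.52% of the counts with vehicle and 2.1 to 2.37% with LCL161. The shares were 1.82 to 1.91% and 1.93 to 2.38% in spleen CD4, 1.22 to 1.43% and 1.35 to 1.39% in tumor CD4 and 1.21 to 1.35% and 1.37 to 1.42% in tumor CD8, ranges over the 3 libraries that overlap in tumor CD4 alone.

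As gene groups in spleen CD8, cell cycle genes were higher (median 1.07, camera adjusted p = 1.4e-11 and adjusted p = 0.76 with an estimated correlation), with 16 higher of 34 members over all genes, 27 higher adjusted over the list alone, among them Pcna, Mcm6, Stmn1 and Tk1. Classical NF-kB targets were higher (median 0.84, camera adjusted p = 0.00015 and adjusted p = 0.76 with an estimated correlation). Of its 21 members 8 higher and 1 lower passed over all genes and 9 higher and 1 lower adjusted over the list alone. Cytotoxic effector genes were higher (median 0.79, camera adjusted p = 0.0015 and adjusted p = 0.76 with an estimated correlation). Over all genes 4 higher of 21 members passed, and 5 higher adjusted over the list alone. Effector cytokines were higher (median 1.27, camera adjusted p = 0.017 and adjusted p = 0.76 with an estimated correlation). Among 16 members 2 higher and 1 lower passed over all genes and 5 higher and 1 lower adjusted over the list alone. The alternative NF-kB pathway list did not pass (median 0.00, camera adjusted p = 0.61 and adjusted p = 0.77 with an estimated correlation) and had 5 higher and 1 lower of 15 members over all genes, 5 higher and 1 lower adjusted over the list alone. Markers of conventional dendritic cells were lower (median -1.49, camera adjusted p = 6.5e-07 and adjusted p = 0.76 with an estimated correlation), with 5 lower of 15 members over all genes, 9 lower adjusted over the list alone, and their sum went from 4310 ± 168 to 1580 ± 448 CPM. MHC class II presentation genes were lower (median -1.01, camera adjusted p = 0.00032 and adjusted p = 0.76 with an estimated correlation). This list has 13 members, with 1 lower over all genes and 6 lower adjusted over the list alone. Neutrophil markers, with 15 of 16 members positive, did not pass (median 1.36, camera adjusted p = 0.11 and adjusted p = 0.77 with an estimated correlation). Of the 36 lists 10 passed camera and 0 with an estimated correlation. The count of 1682 became 534, 815 and 539 without vehicle replicates 1, 2 and 3, 1119 without LCL161 replicate 2 and 244 without LCL161 replicate 3. There 35, 42, 34, 66 and 17 of the 76 named genes past the threshold remained. It was 2590 (1191 higher, 1399 lower) by DESeq2, 7122 (3892 higher, 3230 lower) by limma voom, 961 without a filter and 328 with marker scores of other cells as covariates.

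**Figure D3:**
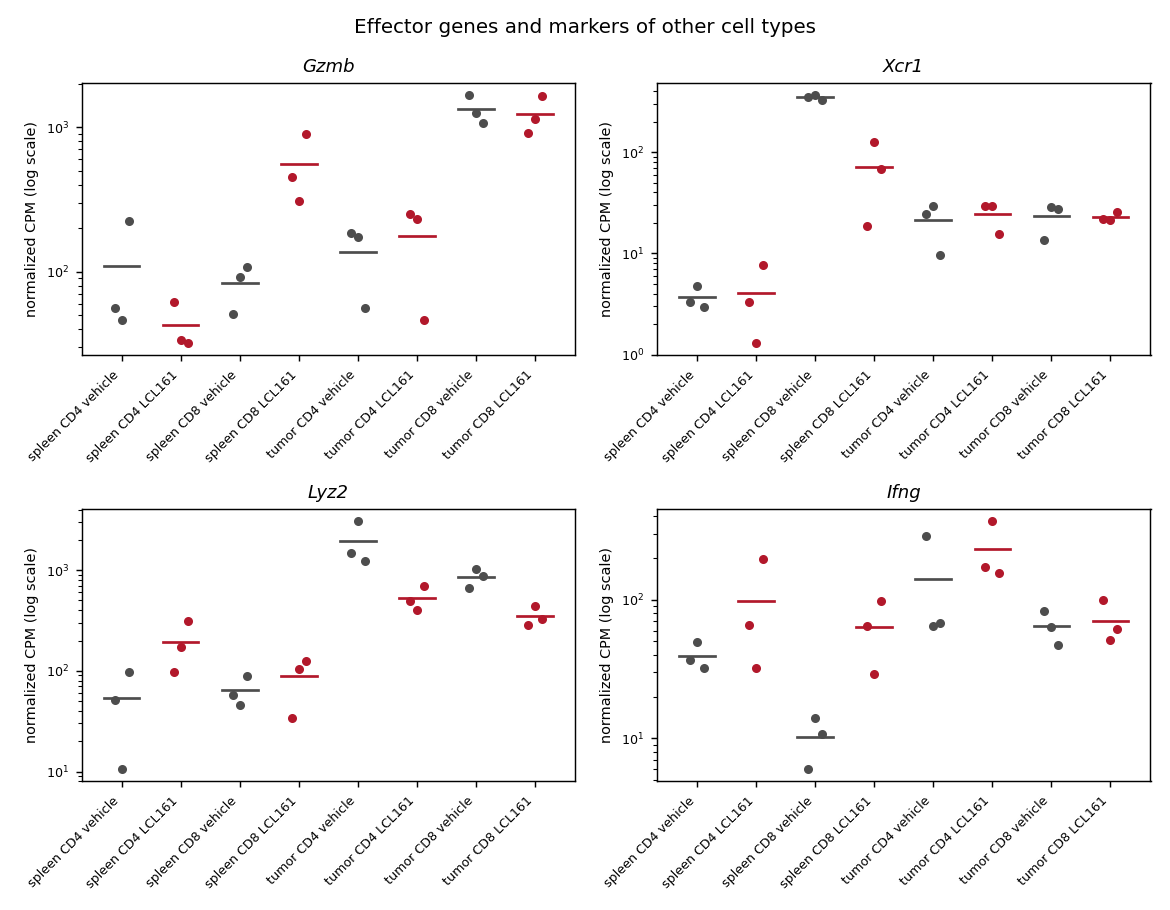
Normalized CPM (log axis) of Gzmb, Xcr1, Lyz2 and Ifng in the 8 groups; points are the 3 libraries, lines the group means, vehicle in grey and LCL161 in red. Gzmb has a mean of 83.5 CPM in spleen CD8 vehicle and 553 CPM in spleen CD8 LCL161.

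In CD4-sorted cells of the tumor LCL161 again raised Icam1, Nfkbia and Relb. Icam1, an adhesion gene, went from 198 ± 42.1 to 578 ± 98.8 CPM (2.93-fold, log2 fold change 1.55 ± 0.22, adjusted p = 0.011). Nfkbia went from 425 ± 68.6 to 1090 ± 136 CPM (1.35 ± 0.19, adjusted p = 0.011) and Relb (chromosome 7, 19606217 to 19629438) from 116 ± 7.44 to 252 ± 25 CPM (1.12 ± 0.18, adjusted p = 0.024). The macrophage receptor gene Csf1r fell from 218 ± 84.1 to 56.3 ± 23.4 CPM (-1.95 ± 0.33, adjusted p = 0.024). In all, 23 genes were higher and 39 lower, 40 of them by at least 2-fold, and with no scaling beyond the library totals 15 were higher and 60 lower. The groups did not overlap for 62 of the 62 genes and for 15.3% of all genes tested, where chance gives 10%. The largest rises on the log2 scale were Wdr95 (2.76), Zc3h12a (2.05), Icam1 (1.55), Gpr18 (1.54), Gramd3 (1.38), Nfkbia (1.35), Mapkapk3 (1.31), Relb (1.12), Bcl3 (1.00) and Birc3 (0.92) (adjusted p 0.011 to 0.047). Traf1 rose by 0.82 and Ier5 by 0.66. The largest falls were Prg4 (-3.42), Cd180 (-2.58), Fcna (-2.51), Lmo2 (-2.44), Cass4 (-2.14), Hmox1 (-2.13), Rab11fip5 (-2.00), Slc7a7 (-2.00), Plekho1 (-1.99) and Cyp4f18 (-1.96) (adjusted p 0.025 to 0.047). Hmox1 encodes heme oxygenase 1, abundant in macrophages that clear red cells. Nrp1 fell by 1.85 and Ctss fell by 1.32. Vwf, an endothelial gene, was called lower at 0.729 ± 0.349 and 0.0313 ± 0.0542 CPM. Nfkb2 was at 276 ± 44.3 and 604 ± 92.6 CPM (adjusted p = 0.051), Birc2 at 71.2 ± 20.6 and 140 ± 28.9 CPM (0.067), Ifng at 141 ± 129 and 231 ± 118 CPM (0.66) and Gzmb at 138 ± 71.4 and 177 ± 113 CPM (0.86), none past the threshold.

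As gene groups in tumor CD4, the alternative NF-kB pathway genes were higher (median 0.46, camera adjusted p = 0.00083 and adjusted p = 0.045 with an estimated correlation). In it 3 higher of 15 members passed over all genes, and 6 higher and 2 lower adjusted over the list alone. Classical NF-kB targets were higher (median 0.52, camera adjusted p = 1.4e-05 and adjusted p = 0.39 with an estimated correlation). Of its 21 members 3 higher passed over all genes and 8 higher adjusted over the list alone. Cell cycle genes were higher (median 0.63, camera adjusted p = 1.6e-10 and adjusted p = 0.49 with an estimated correlation). Over all genes 0 of 34 members passed, and 0 adjusted over the list alone. Monocyte and macrophage markers were lower (median -1.86, camera adjusted p = 2.4e-14 and adjusted p = 0.22 with an estimated correlation), with 1 lower of 22 members over all genes, 18 lower adjusted over the list alone, and their sum went from 8510 ± 3470 to 3220 ± 607 CPM. B cell and plasma cell markers were lower (median -1.85, camera adjusted p = 1.1e-05 and adjusted p = 0.49 with an estimated correlation). Among 16 members 0 passed over all genes and 11 lower adjusted over the list alone. MHC class II presentation genes were lower (median -1.32, camera adjusted p = 0.00012 and adjusted p = 0.49 with an estimated correlation). This list has 13 members, with 1 lower over all genes and 10 lower adjusted over the list alone. Markers of erythroid cells (median -2.74, or -2.71 with members at 0 in a group taken at their bound, camera adjusted p = 0.003 and adjusted p = 0.55 with an estimated correlation), plasmacytoid dendritic cells (median -1.54, camera adjusted p = 0.00021 and adjusted p = 0.49 with an estimated correlation) and endothelium (median -1.03, camera adjusted p = 0.019 and adjusted p = 0.49 with an estimated correlation) were lower too. Markers of conventional dendritic cells (median -1.18, camera adjusted p = 0.069 and adjusted p = 0.8 with an estimated correlation) and gamma delta T cells (median -1.27, camera adjusted p = 0.5 and adjusted p = 0.94 with an estimated correlation) did not pass. Mast cell and basophil markers were higher (median 0.63, camera adjusted p = 0.042 and adjusted p = 0.55 with an estimated correlation). In it 0 of 10 members passed over all genes, and 0 adjusted over the list alone. Of the 36 lists 16 passed camera and 1 with an estimated correlation. The count of 62 became 37 without vehicle replicate 1, 0 without vehicle replicate 2, 370 without vehicle replicate 3, 4 without LCL161 replicate 1 and 6 without LCL161 replicate 2. There 10, 0, 25, 2 and 3 of the 26 named genes past the threshold remained. It was 737 (230 higher, 507 lower) by DESeq2, 122 (39 higher, 83 lower) by limma voom, 24 without a filter, 106 with a stricter filter, 0 with the 6 libraries fitted alone (unadjusted p under 0.05 for 1718 genes) and 0 with marker scores of other cells as covariates (unadjusted p under 0.05 for 1211 genes).

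In CD8-sorted cells of the tumor LCL161 raised genes of both NF-kB arms. Nfkb2 went from 142 ± 19 to 401 ± 76.8 CPM (2.83-fold, adjusted p = 0.014), Birc3 (chromosome 9, 7848699 to 7873186) from 59.5 ± 10.4 to 143 ± 15.6 CPM (1.26 ± 0.17, adjusted p = 0.0032) and Nfkbia from 176 ± 12.3 to 607 ± 113 CPM (1.79 ± 0.19, adjusted p = 0.00041). Gzmb, already at 1330 ± 301 CPM with vehicle, stood at 1230 ± 373 CPM with LCL161 (adjusted p = 0.99), and Ifng at 64.4 ± 18.2 and 70.6 ± 25 CPM (0.98), so neither passed. In all, 47 genes were higher and 3 lower, 37 of them by at least 2-fold. Of the 50 genes 50 had groups that did not overlap, as had 23.6% of all genes tested against 10% by chance. The largest rises on the log2 scale, Nfkb2 aside, were Dyrk3 (3.06), Serpinb1b (2.57), Zc3h12a (2.38), Sept10 (2.18), Nfkbiz (2.09), Irs2 (1.91), Nfkbia (1.79), Odc1 (1.68) and Tsc22d3 (1.65) (adjusted p 0.00041 to 0.037). Nfkbiz encodes an atypical IκB, Odc1 the enzyme that opens polyamine synthesis, and Tsc22d3 the glucocorticoid-induced leucine zipper. Relb rose by 1.25, Bcl3 by 1.22, Icam1 by 1.13, Traf1 by 0.84 and Tnfrsf18, a costimulatory receptor gene, by 1.31. Dtx1, a Notch pathway gene, fell by 1.42 and Rap2b fell by 0.83. Birc2 was at 60.5 ± 5.36 and 87.8 ± 14 CPM (adjusted p = 0.38), Xiap at 20.1 ± 2.82 and 22.5 ± 3.47 CPM (0.88) and Tnf at 12.7 ± 3.3 and 20 ± 5.77 CPM (0.62).

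As gene groups in tumor CD8, the classical NF-kB targets were higher (median 0.65, camera adjusted p = 8.4e-12 and adjusted p = 0.046 with an estimated correlation). Of its 21 members 5 higher passed over all genes and 11 higher adjusted over the list alone. The alternative NF-kB pathway genes were higher (median 0.21, camera adjusted p = 9.8e-05 and adjusted p = 0.013 with an estimated correlation). Over all genes 4 higher of 15 members passed, and 4 higher adjusted over the list alone. Regulatory T cell genes, a list that holds Tnfrsf18, were higher (median 1.10, or 1.13 with members at 0 in a group taken at their bound, camera adjusted p = 0.00036 and adjusted p = 0.49 with an estimated correlation). Among 16 members 1 higher passed over all genes and 5 higher adjusted over the list alone. Type I interferon response genes were lower (median -0.43, camera adjusted p = 1.4e-05 and adjusted p = 0.6 with an estimated correlation). This list has 37 members, with 0 over all genes and 0 adjusted over the list alone. Dissociation stress and immediate early genes were lower (median -0.66, camera adjusted p = 0.00094 and adjusted p = 0.59 with an estimated correlation). In it 0 of 22 members passed over all genes, and 2 higher and 9 lower adjusted over the list alone. Monocyte and macrophage markers were lower (median -1.08, camera adjusted p = 2e-06 and adjusted p = 0.59 with an estimated correlation), with 0 of 22 members over all genes, 2 lower adjusted over the list alone, and B cell and plasma cell markers were higher (median 0.95, camera adjusted p = 0.014 and adjusted p = 0.74 with an estimated correlation). Of the 36 lists 15 passed camera and 2 with an estimated correlation. The count of 50 became 4, 5 and 7 without vehicle replicates 1, 2 and 3, 5 without LCL161 replicate 1 and 4 without LCL161 replicate 2. There 3, 4, 5, 4 and 3 of the 18 named genes past the threshold remained. It was 329 (178 higher, 151 lower) by DESeq2, 687 (377 higher, 310 lower) by limma voom, 240 (154 higher, 86 lower) with the 6 libraries fitted alone and 9 with marker scores of other cells as covariates.

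**Figure D4:**
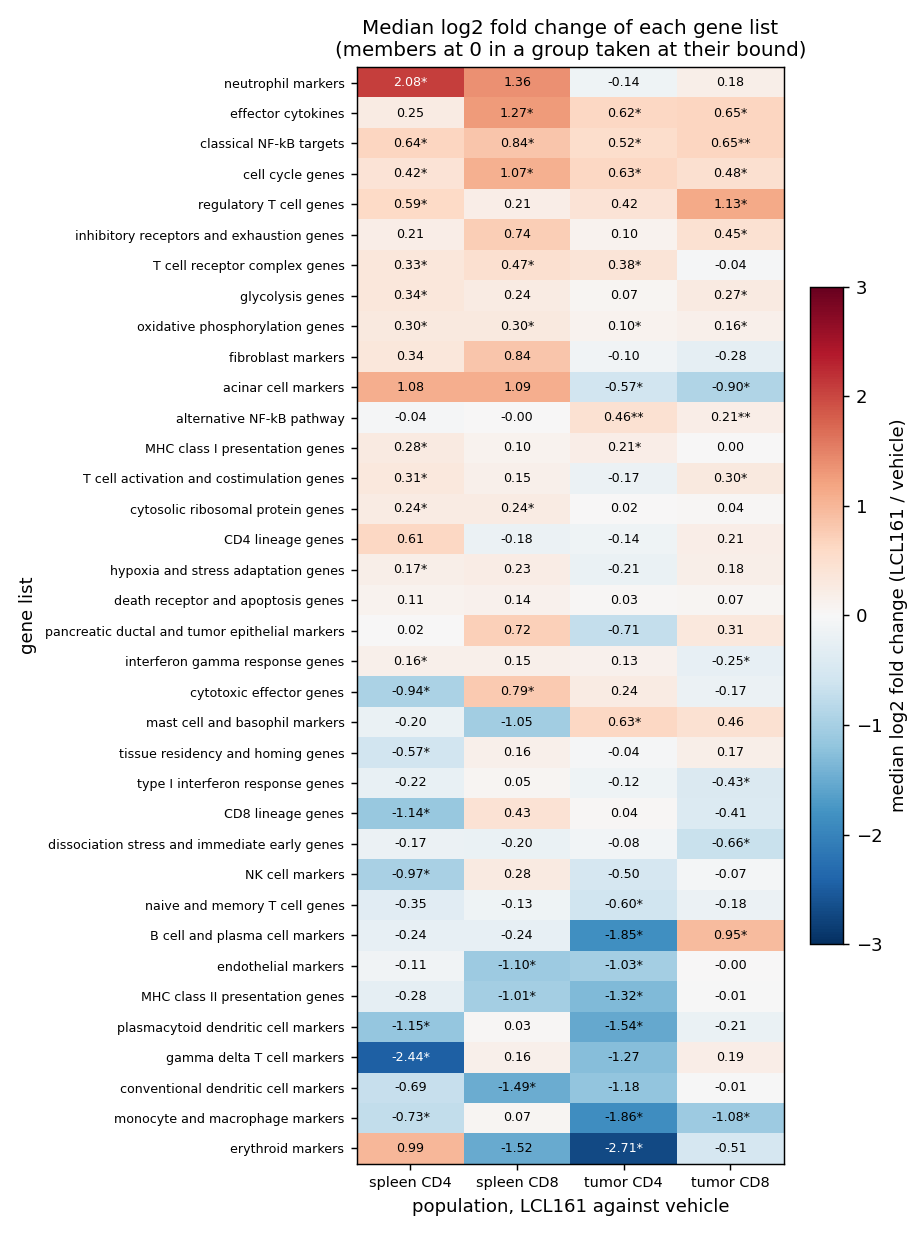
Median log2 fold change of each of the 36 gene lists, LCL161 against vehicle, in the 4 populations; members at 0 in a group are taken at their bound, 1 star marks a camera adjusted p under 0.05 at the preset correlation and a further star the same with an estimated correlation. The monocyte and macrophage list has a median of -1.86 in tumor CD4 and the cell cycle list 1.07 in spleen CD8.

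To ask which genes answered to LCL161 wherever it was measured, calls were compared across the 4 populations. These share no libraries, but share the model's estimate of each gene's spread and possibly mice. More sharing than independent lists give is therefore not separate replication. Higher in all 4 were Bcl3, Birc3, Gm47079, Icam1, Nfkbia, Relb, Rrad, Traf1 and Zc3h12a, 9 genes, among them the NF-kB subunit gene Relb and the inhibitor gene Nfkbia. In the order spleen CD4, spleen CD8, tumor CD4 and tumor CD8, the log2 fold changes were 1.42, 1.76, 1.35 and 1.79 for Nfkbia, 1.89, 1.91, 2.05 and 2.38 for Zc3h12a, 1.08, 0.84, 1.55 and 1.13 for Icam1, 1.09, 0.64, 1.12 and 1.25 for Relb and 0.79, 0.78, 0.92 and 1.26 for Birc3. In 3 populations 9 genes were higher, among them Nfkb2, Tnfrsf18, Tgif1 and Med11, and Rap2b was lower. No gene is called in all 4 where a population has none, as in spleen CD4 without LCL161 replicate 1, in tumor CD4 without vehicle replicate 2 and in both with their 6 libraries fitted alone, and by limma voom at most 2 can be. In 2 populations 39 genes were higher and 20 lower, and 0 genes were called in opposite directions between any 2 populations, by edgeR. Spleen CD4 and spleen CD8 shared 29 higher genes, where independent lists of those sizes give 1.97. Spleen CD8 and tumor CD8 shared 37 against 1.93, tumor CD4 and tumor CD8 12 against 0.0535, and spleen CD4 and tumor CD8 16 against 0.112. Of the falls, again against the number from independent lists, spleen CD4 shared 9 against 1.69 with spleen CD8, 0 against 0.0772 with tumor CD4 and 0 against 0.00594 with tumor CD8. Spleen CD8 shared 12 against 1.64 with tumor CD4 and 1 against 0.127 with tumor CD8, and tumor CD4 and tumor CD8 1 against 0.00579. Over all genes the log2 fold changes of these pairs were correlated by 0.1 to 0.19. Gm47079 lies on the strand opposite Icam1, and Gm16175 opposite Bcl3, so their reads cannot be told apart without the strand setting, which is not given. The same holds for Abca3, Adam15, Cables1, Cass4, Cd180, Cd7, Ctsb, Cxcl10, Eomes, Fcna, Gpr171, Gpr18, Gzmk, Junb, Ltbp2, Maf, Ncald, Nt5dc2, Plet1, Prelp, Rap2b, Rrad, Sdhaf1, Tk1, Tnfrsf18 and Wdfy4. Reads of Cd3e, Ifng, Il1r2, Odc1 and Rab43 share bases with another gene on the same strand, where a strand setting would not part them, and Cd3e and Il1r2 overlap further genes on the opposite strand. Reads of close relatives, such as Trbc1 and Trbc2, the Tcrg constant genes, the Ighg genes and the Serpina3 family, are divided between them with an error that is not given here.

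Whether the response to LCL161 differed between tumor and spleen was tested as the difference of the effects. In CD4-sorted cells 2 genes passed, both with a lower response in the tumor. Adam15 (chromosome 3, 89338542 to 89349996), a metalloprotease gene, went from 6.76 ± 1.03 to 9.64 ± 1.39 CPM in the spleen and from 40.4 ± 12.5 to 15.8 ± 2.63 CPM in the tumor (difference -1.86 ± 0.28, adjusted p = 0.028). Nme4 (chromosome 17, 26091734 to 26095602), a nucleoside diphosphate kinase gene named after its values were seen, went from 1.3 ± 0.0484 to 3.83 ± 1.12 CPM in the spleen and from 3.71 ± 1.36 to 1.14 ± 0.489 CPM in the tumor (difference -3.24 ± 0.49, adjusted p = 0.0276). In CD8-sorted cells 5 genes passed, all with a higher response in the tumor. Abca3 (chromosome 17, 24351950 to 24410201), a lipid transporter gene, differed by 1.79 ± 0.29, Rab43 (chromosome 6, 87788853 to 87812164), a trafficking GTPase gene, by 1.78 ± 0.29 and Mtmr4 (chromosome 11, 87592162 to 87616302), a lipid phosphatase gene, by 1.54 ± 0.25, each with adjusted p = 0.031. With a block for the replicate number 4 genes passed, and of Abca3, Rab43 and Mtmr4 2 remained, with Mtmr4 lost (1.56, adjusted p = 0.071). Libraries of the same number were correlated by more than 0.1 for all 3 numbers only between spleen CD8 LCL161 and tumor CD8 LCL161 (0.12, 0.38 and 0.14). Between spleen CD8 vehicle and tumor CD8 vehicle the correlations were 0.07, 0.29 and 0.02. In the spleen Abca3, Rab43 and Mtmr4 fell, Rab43 from 302 ± 17.6 to 92 ± 36.3 CPM and Mtmr4 from 225 ± 12.2 to 59.5 ± 16.2 CPM, and in the tumor Rab43 had 53.1 ± 7.11 and 55.5 ± 4.97 CPM. The others, Gm8221 (3.65, adjusted p = 0.0128) and Gm45140 (1.55, adjusted p = 0.0138), were also named after their values were seen, and Gm45140 overlaps Rab43 on the same strand. Gzmb differed by -2.83 ± 0.90 in CD8-sorted cells and did not pass (adjusted p = 0.34), nor did Ifng (-2.50 ± 0.91, 0.43) or Nfkb2 (0.71 ± 0.34, 0.55). As a list, conventional dendritic cell markers had a higher response in tumor CD8 than in spleen CD8 (median 1.51, camera adjusted p = 5e-09 and adjusted p = 0.37 with an estimated correlation), with 0 of 15 members over all genes, 5 higher adjusted over the list alone, and cytotoxic effector genes a lower one (median -1.04, camera adjusted p = 8.7e-06 and adjusted p = 0.63 with an estimated correlation). Of its 21 members 0 passed over all genes and 0 adjusted over the list alone. In CD4-sorted cells cytotoxic effector genes had the higher response in the tumor (median 1.10, camera adjusted p = 0.00042 and adjusted p = 0.68 with an estimated correlation). Over all genes 0 of 21 members passed, and 1 higher adjusted over the list alone. The CD4 count of 2 became 0, 3 and 0 without spleen CD4 vehicle replicates 1, 2 and 3, 1, 0 and 21 without spleen CD4 LCL161 replicates 1, 2 and 3, 0, 0 and 7 without tumor CD4 vehicle replicates 1, 2 and 3 and 1, 2 and 2 without tumor CD4 LCL161 replicates 1, 2 and 3, and it was 150 by DESeq2, 1 with a stricter filter, 0 with the 12 libraries fitted alone and 0 with a block for the replicate number. Marker scores as covariates gave 3, with Adam15 not among them. Adam15 passed without a library only where it was spleen vehicle replicate 2 or replicate 3 of spleen LCL161, tumor vehicle or tumor LCL161. The CD8 count of 5 became 2, 1 and 2 without spleen CD8 vehicle replicates 1, 2 and 3, 102, 9 and 0 without spleen CD8 LCL161 replicates 1, 2 and 3, 1, 4 and 0 without tumor CD8 vehicle replicates 1, 2 and 3 and 2, 1 and 11 without tumor CD8 LCL161 replicates 1, 2 and 3, and it was 188 by DESeq2, 837 by limma voom, 112 with the 12 libraries fitted alone, 20 with a stricter filter, 2 with no scaling, where 0 of Abca3, Rab43 and Mtmr4 remained, and 0 with marker scores of other cells as covariates. Without each library in that order 0, 0, 0, 3, 2, 0, 0, 1, 0, 0, 0 and 3 of these 3 remained.

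Whether CD8-sorted and CD4-sorted cells answered differently was tested in the same way. In the spleen 9 genes had a higher and 41 a lower response in CD8-sorted cells. The largest positive differences on the log2 scale were Ncald 2.42, Gadd45g 2.32, Cd7 1.79, Gpr171 1.38, Sla2 0.92 (adjusted p 0.026 to 0.045), and the largest negative ones Palld -4.34, Zbtb46 -3.09, Arrb1 -2.55, Arc -2.52, Fam131a -2.51 (adjusted p 0.026 to 0.038). Cd7, an immunoglobulin superfamily receptor gene of T and NK cells, went from 346 ± 86.7 to 130 ± 33.8 CPM in CD4 and from 303 ± 83.3 to 395 ± 120 CPM in CD8. Zbtb46, a dendritic cell transcription factor gene, went from 10.1 ± 5.85 to 25.2 ± 3.15 CPM in CD4 and from 105 ± 13 to 30.8 ± 6.07 CPM in CD8. Zbtb7b differed by -1.81 ± 0.29 (adjusted p = 0.023) and Tgfb1 by -1.26 ± 0.23 (0.026). Gzmb differed by 4.08 ± 0.92 without passing (adjusted p = 0.064), and so did Trdc (4.61 ± 1.41, 0.16). Cytotoxic effector genes had the higher response in CD8 (median 1.72, camera adjusted p = 3.8e-08 and adjusted p = 0.6 with an estimated correlation). Among 21 members 0 passed over all genes and 8 higher adjusted over the list alone. The gamma delta T cell markers had the higher response in CD8 (median 3.75, camera adjusted p = 0.00012 and adjusted p = 0.66 with an estimated correlation). This list has 14 members, with 0 over all genes and 6 higher adjusted over the list alone. The count of 50 became 16, 56 and 14 without spleen CD4 vehicle replicates 1, 2 and 3, 35, 58 and 213 without spleen CD4 LCL161 replicates 1, 2 and 3, 0, 27 and 0 without spleen CD8 vehicle replicates 1, 2 and 3 and 313, 28 and 1 without spleen CD8 LCL161 replicates 1, 2 and 3, and it was 512 by DESeq2, 549 by limma voom, 129 with a stricter filter, 4 with the 12 libraries fitted alone and 0 with marker scores of other cells as covariates (unadjusted p under 0.05 for 1741 genes). Of the 12 named genes past the threshold 3, 6, 3, 5, 8, 12, 0, 0, 0, 12, 7 and 0 remained without each library in that order, 2 with the 12 libraries fitted alone and 0 with the scores. In the tumor edgeR called 0 genes, DESeq2 41 and limma voom 0. The unadjusted p in edgeR was under 0.05 for 1126 of 20203 genes, where chance gives a share of 0.05. The edgeR count was 1 without tumor CD4 vehicle replicate 1 and 1 without tumor CD4 LCL161 replicate 2. Nfkb2 differed there by 0.37 ± 0.34 (adjusted p = 0.95) and Nfkbia was called higher in both populations. B cell and plasma cell markers had the higher response in tumor CD8 (median 2.69, camera adjusted p = 4.3e-10 and adjusted p = 0.57 with an estimated correlation). In it 0 of 16 members passed over all genes, and 9 higher adjusted over the list alone.

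Tumor and spleen were compared in the vehicle libraries. In CD4-sorted cells Lyz2, the lysozyme gene of myeloid cells, had 53.2 ± 43.7 CPM in the spleen and 1930 ± 984 CPM in the tumor (36.3-fold, log2 fold change 5.18 ± 0.70, adjusted p = 8.9e-05). Tnf rose from 14.4 ± 5.24 to 70.8 ± 39.5 CPM (2.29 ± 0.44, adjusted p = 0.0017). In all, 1954 genes were higher and 1384 lower, 2263 of them by at least 2-fold. Separate groups were found for 3082 of the 3338 genes and 31.0% of all genes, against 10% by chance. The 10 genes at the top had no count in the spleen libraries. Against the floor of 3 counts per library the tumor was higher by at least these sizes: Aqp5 385-fold, Ccl7 385-fold, Ccl2 372-fold, Tpsb2 286-fold, Sparc 233-fold, Tm4sf1 223-fold, Fbln2 197-fold, Nfib 169-fold, Plet1 169-fold and Trem2 160-fold (adjusted p 4.1e-05 to 0.00065). Ccl2 and Ccl7 encode monocyte chemokines and Tpsb2 a mast cell tryptase. At the other end, genes with no count in the tumor were lower by at least these sizes: Slc4a1 154-fold, Elane 68.2-fold, Npy 62.5-fold, Car1 62.4-fold and Ecel1 39.8-fold. Sostdc1 went from 172 ± 163 to 0.434 ± 0.752 CPM, Serpina9 from 16.1 ± 14.5 to 0.0482 ± 0.0835 and Itgb8 from 29.7 ± 18.5 to 0.147 ± 0.139 CPM. Monocyte and macrophage markers were higher (median 4.74, camera adjusted p = 2.4e-20 and adjusted p = 0.048 with an estimated correlation). Of its 22 members 18 higher passed over all genes and 18 higher adjusted over the list alone. Glycolysis genes were higher (median 1.63, camera adjusted p = 6.2e-20 and adjusted p = 0.048 with an estimated correlation), with 18 higher of 20 members over all genes, 19 higher adjusted over the list alone, and so were hypoxia and stress adaptation genes (median 2.19, camera adjusted p = 1e-09 and adjusted p = 0.012 with an estimated correlation). Over all genes 10 higher of 15 members passed, and 12 higher adjusted over the list alone. Acinar cell markers were higher (median 7.11, or 4.57 with members at 0 in a group taken at their bound, camera adjusted p = 4.5e-10 and adjusted p = 0.19 with an estimated correlation), with 15 higher of 17 members over all genes, 15 higher adjusted over the list alone, and B cell and plasma cell markers lower (median -3.73, camera adjusted p = 7.8e-17 and adjusted p = 0.075 with an estimated correlation). Among 16 members 16 lower passed over all genes and 16 lower adjusted over the list alone. Trac, at 328 ± 229 and 338 ± 249 CPM, did not pass (adjusted p = 0.97). The count of 3338 became 1899 without spleen vehicle replicate 1, 2141 without spleen vehicle replicate 3, 899 with the 6 libraries fitted alone and 0 with marker scores of other cells as covariates, which themselves separate the tissues (unadjusted p under 0.05 for 606 genes; DESeq2 called 4062 and limma voom 2646 without the scores).

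In CD8-sorted cells, again with vehicle, Gzmb had 83.5 ± 29.4 CPM in the spleen and 1330 ± 301 CPM in the tumor (15.9-fold, log2 fold change 3.99 ± 0.70, adjusted p = 0.00083), and Ifng 10.3 ± 4.05 and 64.4 ± 18.2 CPM (2.64 ± 0.67, adjusted p = 0.011). Lyz2 was higher, at 64 ± 21.8 and 856 ± 182 CPM (adjusted p = 0.00079), and Cd3e too, at 540 ± 23.7 and 1080 ± 76.7 CPM (0.0011). Birc3 was lower, at 99.3 ± 15.2 and 59.5 ± 10.4 CPM (-0.74 ± 0.17, adjusted p = 0.0052). In all, 1616 genes were higher and 1392 lower, 1957 of them by at least 2-fold. The groups did not overlap for 2989 of the 3008 genes and for 47.8% of all genes tested, where chance gives 10%. The 10 genes at the top had no count in the spleen libraries and were higher by at least these sizes: Ccl12 177-fold, Ccl7 153-fold, Ccl8 132-fold, Mmp13 130-fold, Nfib 101-fold, Trem2 75.5-fold, Prelp 74.4-fold, Col6a1 67.4-fold, Sox9 59.3-fold and Mgp 52.1-fold (adjusted p 6.2e-05 to 0.0015). Immunoglobulin genes led the falls. Ighg1, with no count in the tumor, was at least 2880-fold lower, Ighg2b went from 272 ± 177 to 0.0136 ± 0.0235 CPM, Igha from 616 ± 564 to 0.0582 ± 0.0686, Ighg2c from 966 ± 772 to 0.11 ± 0.153 and Jchain from 621 ± 235 to 0.264 ± 0.208 CPM. Type I interferon response genes were higher (median 1.80, camera adjusted p = 7.5e-19 and adjusted p = 0.15 with an estimated correlation). This list has 37 members, with 29 higher over all genes and 32 higher adjusted over the list alone. Cytotoxic effector genes were higher (median 1.11, camera adjusted p = 1.9e-06 and adjusted p = 0.16 with an estimated correlation). In it 9 higher of 21 members passed over all genes, and 13 higher adjusted over the list alone. Monocyte and macrophage markers were higher (median 3.65, camera adjusted p = 1.2e-15 and adjusted p = 0.099 with an estimated correlation). Of its 22 members 18 higher and 1 lower passed over all genes and 20 higher and 1 lower adjusted over the list alone. B cell and plasma cell markers were lower (median -5.63, camera adjusted p = 3.1e-21 and adjusted p = 0.099 with an estimated correlation), with 15 lower of 16 members over all genes, 16 lower adjusted over the list alone, and so were MHC class II presentation genes (median -3.01, camera adjusted p = 5.8e-11 and adjusted p = 0.12 with an estimated correlation). Over all genes 10 lower of 13 members passed, and 11 lower adjusted over the list alone. The count of 3008 became 1906 without tumor vehicle replicate 1, 7120 by limma voom, 5790 with the 6 libraries fitted alone, 1780 in the LCL161 libraries and 0 with marker scores of other cells as covariates (unadjusted p under 0.05 for 487 genes; DESeq2 called 3638 without the scores).

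The sorted populations were compared with each other in vehicle libraries as a check of the sort and of what else the gates hold. In the spleen Cd8a was 279-fold higher in CD8-sorted cells (log2 fold change 8.13 ± 0.63, adjusted p = 3.7e-07) and Cd4 116-fold lower (-6.85 ± 0.38, adjusted p = 6.1e-09). Trac fell by 4.99 ± 0.70 on the log2 scale (adjusted p = 0.00016), Trbc2 fell by 1.34 and Cd3e fell by 0.77, while Trdc (1.05 ± 0.96) did not pass (adjusted p = 0.56). In all, 1082 genes were higher in CD8-sorted cells and 1240 lower, 1515 of them by at least 2-fold. With no scaling beyond the library totals 903 were higher and 1515 lower, and with marker scores as covariates 38 and 220. Of the 2322 genes 2261 had groups that did not overlap, as had 36.3% of all genes tested against 10% by chance. At the top, Gpr141b had 0.0165 ± 0.0286 CPM in CD4 and 153 ± 33.5 CPM in CD8. Genes with no count in CD4-sorted cells were higher by at least these sizes: Sult1a1 270-fold, Mab21l3 95.4-fold and Ltbp2 58-fold. Genes with no count in CD8-sorted cells were lower by at least these sizes: Rasd2 234-fold, Ccn5 207-fold, Bace2 134-fold and Ascl2 117-fold. CD4 lineage genes were lower in CD8-sorted cells (median -2.49, camera adjusted p = 9.5e-13 and adjusted p = 0.00064 with an estimated correlation). Among 10 members 8 lower passed over all genes and 9 lower adjusted over the list alone. Regulatory T cell genes were lower (median -2.40, camera adjusted p = 3.1e-09 and adjusted p = 0.045 with an estimated correlation), with 11 lower of 16 members over all genes, 1 higher and 13 lower adjusted over the list alone, and so were T cell activation and costimulation genes (median -1.38, camera adjusted p = 2.9e-08 and adjusted p = 0.045 with an estimated correlation). This list has 20 members, with 1 higher and 11 lower over all genes and 1 higher and 12 lower adjusted over the list alone. Conventional dendritic cell markers were higher (median 3.01, camera adjusted p = 7.5e-12 and adjusted p = 0.096 with an estimated correlation). In it 11 higher of 15 members passed over all genes, and 12 higher and 1 lower adjusted over the list alone. Cytosolic ribosomal protein genes were higher by a small amount (median 0.51, camera adjusted p = 1.2e-14 and adjusted p = 0.35 with an estimated correlation). Of its 38 members 20 higher passed over all genes and 37 higher adjusted over the list alone. The count of 2322 became 1310, 1510 and 1363 without CD8 vehicle replicates 1, 2 and 3, 1424 without CD4 vehicle replicate 1, 4459 by limma voom, 3522 in the LCL161 libraries and 258 with marker scores of other cells as covariates.

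In the tumor the same comparison put cytotoxic genes on the CD8 side and glycolysis and mast cell genes on the CD4 side. Cd8a was 626-fold higher in CD8-sorted cells (log2 fold change 9.29 ± 0.66, adjusted p = 2.3e-07), and Gzmb had 138 ± 71.4 CPM in CD4 and 1330 ± 301 CPM in CD8 (3.26 ± 0.68, adjusted p = 0.0095). Trac had 338 ± 249 CPM in CD4 and 20.7 ± 2.64 CPM in CD8 (-4.03 ± 0.66, adjusted p = 0.002), and Tnf 70.8 ± 39.5 and 12.7 ± 3.3 CPM (-2.48 ± 0.44, adjusted p = 0.0032). In all, 344 genes were higher in CD8-sorted cells and 488 lower, 577 of them by at least 2-fold. Separate groups were found for 814 of the 832 genes and 25.8% of all genes, against 10% by chance. After Cd8a, the largest differences toward CD8 on the log2 scale were Ppp2r2c (4.84), Cd8b1 (4.65), Gzmk (4.47), Klre1 (4.44), Eomes (4.41), S1pr5 (4.33), Ifngas1 (4.28), Sox13 (4.24) and Wdr31 (4.16) (adjusted p 0.00067 to 0.03). Gzmk encodes a granzyme, Eomes a transcription factor of cytotoxic cells and Klre1 an NK receptor. Toward CD4 they were Tpsb2 (-8.71), Ighg2c (-8.23), Pcsk1 (-7.80), Ccr4 (-7.62), Gzmf (-6.84), Ermn (-6.14), Cd40lg (-6.01), Cd4 (-5.61), St6galnac1 (-5.59) and Galnt9 (-5.47) (adjusted p 7.1e-08 to 0.047). Cd40lg encodes the CD40 ligand and Ccr4 a receptor of helper T cells. CD8 lineage genes were higher (median 3.13, camera adjusted p = 2.3e-15 and adjusted p = 0.0096 with an estimated correlation), with 8 higher of 10 members over all genes, 10 higher adjusted over the list alone, and so were cytotoxic effector genes (median 2.15, camera adjusted p = 1.7e-14 and adjusted p = 0.041 with an estimated correlation). Over all genes 12 higher and 1 lower of 21 members passed, and 16 higher and 1 lower adjusted over the list alone. CD4 lineage genes were lower (median -1.98, camera adjusted p = 2.3e-10 and adjusted p = 0.0024 with an estimated correlation). Among 10 members 5 lower passed over all genes and 5 lower adjusted over the list alone. Glycolysis genes were lower (median -0.98, camera adjusted p = 9.4e-16 and adjusted p = 0.041 with an estimated correlation). This list has 20 members, with 13 lower over all genes and 17 lower adjusted over the list alone. Hypoxia and stress adaptation genes were lower (median -1.31, camera adjusted p = 1e-07 and adjusted p = 0.013 with an estimated correlation), with 6 lower of 15 members over all genes, 1 higher and 12 lower adjusted over the list alone, and so were mast cell and basophil markers (median -4.26, camera adjusted p = 9.4e-09 and adjusted p = 0.038 with an estimated correlation). In it 5 lower of 10 members passed over all genes, and 8 lower adjusted over the list alone. The count of 832 became 237, 527 and 382 without CD8 vehicle replicates 1, 2 and 3, 1597 by DESeq2, 1412 by limma voom, 167 with the 6 libraries fitted alone and 217 with marker scores of other cells as covariates.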

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

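The differences of treatment effects below were planned, while the tests of explanations and the counts over other splits of the samples were chosen after the results were seen. The response to LCL161 differed between tumor and spleen for 2 genes in CD4-sorted cells and 5 in CD8-sorted cells, and between CD8 and CD4 for 50 genes in the spleen. The log2 differences, tumor minus spleen, were -1.86 for Adam15 and -3.24 for Nme4 in CD4, and in CD8 3.65 for Gm8221, 1.55 for Gm45140, 1.79 for Abca3, 1.78 for Rab43 and 1.54 for Mtmr4, with Nme4, Gm8221 and Gm45140 named after their values were seen. With a block for the replicate number 0 genes passed in CD4 and 4 in CD8. For CD8 minus CD4 in the spleen 12 of the 50 are named, Ncald (2.42), Gadd45g (2.32), Cd7 (1.79), Gpr171 (1.38), Sla2 (0.92), Palld (-4.34), Zbtb46 (-3.09), Arrb1 (-2.55), Arc (-2.52), Fam131a (-2.51), Tgfb1 (-1.26) and Zbtb7b (-1.81). Of the 36 lists, camera at its preset correlation called 15 between tissues in CD4, 17 in CD8, 11 between populations in the spleen and 18 in the tumor, and 0 in each with an estimated correlation and by fry.

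Other splits of the same libraries gave as many genes as the real one in 6 of 33 for tumor minus spleen in CD4 (real 2, highest other 604), 7 of 33 in CD8 (5 and 533), 4 of 33 for CD8 minus CD4 in the spleen (50 and 330) and 33 of 33 in the tumor (0 and 0). Chance is not excluded for the count in CD4, and the splits do not test it for the others. In CD8 and in the spleen every other split that reached the real count kept or exchanged all labels of spleen CD8 and so carries its treatment effect, and in the tumor the real count is 0. The number of splits drawn for these was raised once, after the result of a smaller draw had been seen. Splits that call several times the real count point to a structure of the samples, which here can be the treatment, since exchanging the labels of one population turns a difference of effects toward their sum. The split with 604 genes kept 3 of 3 labels in tumor CD4 and 0 of 3 in spleen CD4. For the 8 contrasts of 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each. The real count and the highest of the others were 88 against 12 in spleen CD4, 1682 against 0 in spleen CD8, 62 against 7 in tumor CD4 and 50 against 0 in tumor CD8 for LCL161. They were 3338 against 116 for tumor against spleen in CD4, 3008 against 0 in CD8, 2322 against 0 for CD8 against CD4 in the spleen and 832 against 1 in the tumor.

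In spleen CD8, 11 of 58 genes of the cytotoxic, activation and inhibitory receptor lists passed as higher with LCL161 and 5 of 15 dendritic cell markers as lower, in cells sorted as CD45+CD8+ with no CD3 gate stated. Dilution of dendritic cell RNA by T cell RNA alone is argued against, since the B and plasma cell list lies 1.25 above the dendritic list in median (SD 0.49 and 0.86). A larger share of T cell RNA of unchanged makeup cannot be told apart from a change within T cells for the 58 genes. Their median lies 0.22 above that of the receptor complex list (SD 0.31), and the members go both ways, with SD 1.05 and 17 negative. A first test on the called members alone was dropped, as they were chosen for their rise. A candidate explanation for the dendritic cell markers is less dendritic cell RNA in the gate, with 15 of 15 markers negative and a median of -1.49, among them Irf8 at 1490 ± 56.9 and 524 ± 155 CPM and Wdfy4 at 732 ± 13.3 and 73.6 ± 26.7 CPM. Irf8 and Ccr7 of this list belong to T cell lists as well, and whether cell number or RNA per cell changed stays open.

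In tumor CD4, monocyte and macrophage markers were lower with LCL161 as a list (camera adjusted p = 2.4e-14, and 0.22 with an estimated correlation), with 1 of 22 past the threshold over all genes. Tumor CD4 vehicle replicate 2 alone is argued against as the source of the list's fall, since its median without that library is -1.44, although the count of genes past the threshold was 0 without it. Less myeloid RNA in the gate may be the source, with 22 of 22 markers negative, from -2.39 (Ms4a7) to -0.02 (Ccr2), and a median of -1.86. The most abundant were Lyz2, at 1930 ± 984 and 530 ± 155 CPM, and Ctsb, at 1570 ± 547 and 852 ± 106 CPM, and Ccr2 is held by a T cell list too. Other lists past camera at its preset correlation were B and plasma cell (median -1.85), erythroid (-2.74), plasmacytoid dendritic (-1.54) and endothelial markers (-1.03), with adjusted p = 0.49, 0.55, 0.49 and 0.49 at an estimated correlation. Dilution of other cells by more T cell RNA cannot be told apart from it, since the B and plasma cell list lies 0.02 from the myeloid list in median (SD 1.71 and 0.64), while neutrophil (-0.14) and mast cell markers (0.63) did not fall alike. An effect of LCL161 on gene expression within myeloid cells was not tested and stays open.

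In spleen CD4, gamma delta T cell markers were lower with LCL161 as a list (camera adjusted p = 2.4e-06, and 0.39 with an estimated correlation), with 2 of 14 past the threshold over all genes. Carry-over from the CD8 gate is argued against, since Cd8a in the vehicle libraries, 1.11 to 3.98 CPM, reaches at most 2.08% of the 62.1 to 543 CPM that their Trdc implies. The CD8 lineage list, with a median of -1.14, and the NK cell list (-0.97) passed camera at the preset correlation and had adjusted p = 0.39 with an estimated one, with 0 members of either past the threshold over all genes. Fewer gamma delta T cells among the CD4-sorted cells cannot be told apart from lower expression per cell, and the directional rotation test on the list has adjusted p = 0.068 with 3 libraries a group. Trdc had 279, 65.3 and 571 CPM in the vehicle libraries and 8, 39.4 and 15 CPM with LCL161. Maf, Il17a and Zbtb16 of this list are also expressed by other T cells.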

How the results depend on the processing

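The alternatives were planned, except the marker scores, added after the data were seen. After an earlier run reversed named genes between tissues and between populations, where the scores themselves separate the groups, single genes under that setting were limited to treatment effects and their differences. Named genes past the threshold were counted once per contrast. They stayed past it for 631 of 633 under DESeq2, 619 of 619 under the stricter filter and 625 of 634 without scaling. The number was 616 of 634 under RLE scaling, 574 of 634 with the replicate block and 551 of 634 without a filter. It was 545 of 634 with a log2 fold change of at least 1 and 542 of 634 under limma voom. It was 430 of 626 with only the libraries compared, 2875 of 3900 refits without a library and 30 of 169 with the scores. Of those not past it, 23 passed under DESeq2, 18 under limma voom, 14 with only the libraries compared, 7 under the stricter filter, 4 with the replicate block, 1 without scaling, 1 with the scores and 12 refits without a library. Of named genes past the threshold 0 reversed. This leaves out the earlier reversals, and LCL161 in place of vehicle was not read by gene. For LCL161 in spleen CD4 and tumor CD4, limma voom kept 1 of 33 and 22 of 26. Only the libraries compared kept 0 of 33 and 0 of 25. In spleen CD8 and tumor CD8 these were 74 of 76 and 18 of 18, and 66 of 74 and 18 of 18.

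Counts of genes past the threshold moved by more than 1.5 times as follows, from 88 (spleen CD4), 1682 (spleen CD8), 62 (tumor CD4), 50 (tumor CD8), 2 (tumor minus spleen CD4), 5 (tumor minus spleen CD8), 50 (CD8 minus CD4 spleen), 0 (CD8 minus CD4 tumor), 3338 (tumor against spleen CD4), 3008 (tumor against spleen CD8), 2322 (CD8 against CD4 spleen) and 832 (CD8 against CD4 tumor) as reported. DESeq2 gave 651 (spleen CD4), 2590 (spleen CD8), 737 (tumor CD4), 329 (tumor CD8), 150 (tumor minus spleen CD4), 188 (tumor minus spleen CD8), 512 (CD8 minus CD4 spleen), 41 (CD8 minus CD4 tumor) and 1597 (CD8 against CD4 tumor). Limma voom gave 2 (spleen CD4), 7122 (spleen CD8), 122 (tumor CD4), 687 (tumor CD8), 837 (tumor minus spleen CD8), 549 (CD8 minus CD4 spleen), 7120 (tumor against spleen CD8), 4459 (CD8 against CD4 spleen) and 1412 (CD8 against CD4 tumor). Only the libraries of the groups compared gave 0 (spleen CD4), 0 (tumor CD4), 240 (tumor CD8), 0 (tumor minus spleen CD4), 112 (tumor minus spleen CD8), 4 (CD8 minus CD4 spleen), 899 (tumor against spleen CD4), 5790 (tumor against spleen CD8) and 167 (CD8 against CD4 tumor). Marker scores as covariates gave 52 (spleen CD4), 328 (spleen CD8), 0 (tumor CD4), 9 (tumor CD8), 0 (tumor minus spleen CD8), 0 (CD8 minus CD4 spleen), 0 (tumor against spleen CD4), 0 (tumor against spleen CD8), 258 (CD8 against CD4 spleen) and 217 (CD8 against CD4 tumor). Without a filter on low counts there were 49 (spleen CD4), 961 (spleen CD8) and 24 (tumor CD4), and with at least 5 CPM in 3 or more libraries, where fewer genes are tested, 106 (tumor CD4), 1 (tumor minus spleen CD4), 20 (tumor minus spleen CD8) and 129 (CD8 minus CD4 spleen). A log2 fold change of at least 1, which can only remove genes, left 749 (spleen CD8), 40 (tumor CD4), 1957 (tumor against spleen CD8) and 1515 (CD8 against CD4 spleen). No scaling gave 2 (tumor minus spleen CD8), and LCL161 libraries in place of vehicle 1780 (tumor against spleen CD8) and 3522 (CD8 against CD4 spleen). For the settings other than the stricter filter and the minimum fold the cause was not tested. Where edgeR gave 0 with only the libraries compared, the unadjusted p was under 0.05 for 1417, 1718 and 1068 genes. With the scores it was so for 1211, 995, 1741, 606 and 487 genes, in the order above. Chance alone gives a share of 0.05 of the genes tested.

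Leaving out each library in turn gave, in the order of the counts as reported, 0 to 226, 244 to 1706, 0 to 370, 4 to 42, 0 to 21, 0 to 102, 0 to 313, 0 to 1, 1899 to 3326, 1906 to 2184, 1310 to 1873 and 237 to 969. Libraries moving a count by over 1.5 times are named above. A group left with 2 libraries is tested with the pooled spread.

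Whether libraries with one replicate number belong together is not stated, so pairing was not used in the main fit. In a check over 10226 genes, the deviations of libraries with the same number from their group means were correlated by more than 0.1 for all 3 numbers in 1 of the 12 same-arm pairs of groups, spleen CD8 LCL161 with tumor CD8 LCL161 (0.12, 0.38 and 0.14). With the replicate number as a block the count was 0 (tumor minus spleen CD4), with an unadjusted p under 0.05 for 1958 genes.

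Lists past camera at the preset correlation numbered 19 (spleen CD4), 10 (spleen CD8), 16 (tumor CD4), 15 (tumor CD8), 15 (tumor minus spleen CD4), 17 (tumor minus spleen CD8), 11 (CD8 minus CD4 spleen), 18 (CD8 minus CD4 tumor), 21 (tumor against spleen CD4), 25 (tumor against spleen CD8), 14 (CD8 against CD4 spleen) and 22 (CD8 against CD4 tumor). With an estimated correlation they numbered, in the same order, 0, 0, 1, 2, 0, 0, 0, 0, 3, 0, 3 and 6. By fry they numbered, in the same order, 2, 2, 3, 2, 0, 0, 0, 0, 21, 25, 12 and 14. Leaving out each library in turn gave, in the same order, 17 to 21, 10 to 13, 12 to 19, 13 to 17, 8 to 17, 13 to 18, 9 to 12, 11 to 21, 19 to 22, 25 to 26, 13 to 15 and 18 to 25 lists. None of the lists past camera changed direction under RLE scaling.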

Other observations

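These values were chosen after the data were seen and were not tested. In the beta chain variable segments, no group had the same segment with the most counts in all 3 libraries. In replicates 1, 2 and 3 it was Trbv12-2 (89.9%), Trbv3 (39.6%) and Trbv12-1 (78.2%) of the sum in spleen CD4 vehicle, Trbv12-1 (82.8%), Trbv12-2 (71.6%) and Trbv12-1 (49.7%) in spleen CD4 LCL161, Trbv13-1 (55.2%), Trbv13-3 (36.5%) and Trbv3 (63.2%) in tumor CD4 vehicle and Trbv12-2 (62.9%), Trbv13-2 (27.8%) and Trbv5 (76.2%) in tumor CD4 LCL161. It was Trbv16 (10.8%), Trbv1 (13.3%) and Trbv20 (14%) in spleen CD8 vehicle and Trbv13-2 (10.3%), Trbv29 (9.75%) and Trbv14 (10.8%) in spleen CD8 LCL161. In tumor CD8 it was Trbv15 (62.2%), Trbv17 (55%) and Trbv20 (20.4%) with vehicle and Trbv14 (14.6%), Trbv29 (22.7%) and Trbv13-2 (16.4%) with LCL161.

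Foxp3 had 8.82, 189 and 2.93 CPM in replicates 1, 2 and 3 of spleen CD4 LCL161, and 7.23, 42.1 and 3.48 CPM in spleen CD4 vehicle. Tpsb2 had 44.7 ± 51.9 CPM in tumor CD4 vehicle and 76.1 ± 40.9 CPM in tumor CD4 LCL161, against 0.103 ± 0.144 and 0.139 ± 0.241 CPM in tumor CD8. Markers of acinar cells, the enzyme-secreting cells of the pancreas, summed to 103 ± 48.4 CPM in tumor CD4 vehicle, 44.5 ± 20.6 CPM in tumor CD8 vehicle, 15.3 ± 2.56 CPM in spleen CD4 vehicle and 4.44 ± 1.48 CPM in spleen CD8 vehicle.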
